A study of Homo sapiens with 3 samples.

How the data were processed

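Total RNA from HMEC-1 cells cultured for 72 h with 0, 0.1 or 1 µM erlotinib was extracted with Trizol and labelled with Cy3 by Agilent's low-input method, per the labels' protocols. Each sample was read on 1 array (3 arrays, all on 1 slide and in 1 scan), with 1 RNA sample per array and no replicate of any dose. The arrays carry 62976 spots, of which 58717 are not controls, for 50599 probes of 60 bases (design 039494). Per the file headers, spot intensities were extracted with Agilent Feature Extraction 10.5.1.1 on a grid built on hg19 (GRCh37), with background subtraction, spatial and multiplicative detrending, and surrogate values for spots not above background. The deposited table of intensity values equals these processed signals at all 58717 spots of each array, so it is linear, uncentred and not scaled between arrays, with medians of 122, 202 and 164 at 0, 0.1 and 1 µM. These values are single-channel levels, so no direction had to be settled. The passage number of the cells, the vehicle at 0 µM and RNA integrity values are not given in the sources used here.

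For the values in the text, the log2 of the processed signal was taken relative to the 75th percentile of the non-control spots of its array. Spots flagged as outliers were left out (291, 289 and 272 at 0, 0.1 and 1 µM), no spot was saturated, and the spots of a repeated probe were averaged. Probes were named by the current symbol of their accession in a RefSeq table (30004 probes), by the symbol of another probe with the same name in the file (2356), or by the file's own name (18239), which gave 28606 symbols. That table was used for names only, and coordinates are the file's own. A gene with several probes (8550 symbols) was represented by its brightest probe over the 3 arrays. A gene counted as measured in a comparison when that probe was well above background on both arrays by the scanner's flag. The median ratio of raw signal to background was 6.95, 10.4 and 9.42, the lowest signal well above background was 20.4, 19.7 and 22.9, and 23077, 24954 and 23739 genes were well above background. For a gene well above background on a single array of a comparison, a bound is given, with the dim side set to the higher of its own signal and the lowest signal well above background on that array. Of 902 probes with 10 spots, those measured (800 to 840 an array) gave median SDs between spots of 0.0995, 0.0820 and 0.0732 (log2), with 95th percentiles of 0.543, 0.346 and 0.331.

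The comparisons were 1 minus 0, 0.1 minus 0 and 1 minus 0.1 µM. With 1 array per dose there is no spread between replicates, so no test was made and no p-value is given. The threshold of 2-fold is descriptive. There were 26 gene lists (505 entries, 2 genes of them without a probe), fixed before the data were examined: ERBB receptors and ligands, ERK pathway output, IQGAP family and partners, endothelial junctions, endothelial identity, lymphatic, epithelial and keratinocyte, fibroblast and mural, and leukocyte markers, leukocyte adhesion and cytokines, interferon-stimulated genes, G2/M, DNA replication, p53 targets, BCL2 family, cholesterol synthesis and uptake, integrated stress and unfolded protein response, hypoxia and glycolysis, extracellular matrix and proteolysis, angiogenesis and Notch, haemostasis, aryl hydrocarbon receptor and NRF2 targets, heat shock proteins, TGF-β and BMP response, ribosomal proteins, and the mitochondrial respiratory chain. Each list's median difference was placed among 10000 random lists of the same size, drawn from measured genes in the same 20 bins of signal. These percentiles describe where a list lies and are not tests, since genes of a list are not independent. Another 8 marker sets (red cell, myeloid, T and NK, B, hepatocyte, neuron and glia, testis germ cell, striated muscle) and the olfactory receptor genes were read for cell types that the line should lack.

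Genes are named by a rule also fixed beforehand: IQGAP1 to IQGAP3, EGFR, ERBB2 and ERBB3; the 12 largest differences each way at each dose from 0 µM and the 5 each way between the doses, among genes of at least median signal whose other probes differ in the same direction; the 6 each way largest at both doses; up to 4 members of each list per dose; and the 3 largest bounds each way. This gave 172 genes. List members outside the rule (ADM, CCND1, CDH5, CRELD2, CXCL2, DUSP6, EGFL7, ETV4, ETV5, HERPUD1, KRT7, MYC, OASL, TRIB3 and VWF, and PTGS2, SELE and VCAM1 as not measured), the trend-removed values of single genes and the EGFR, ERBB2 and ERBB3 probes beyond the brightest were chosen after their values were seen.

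The relation of the doses was described by the correlation across genes of their differences from the same array, with each of the 3 arrays as the reference in turn, beside arrays simulated with spot noise alone. Position along the transcript, GC content and signal of the probe were related to the differences by cubic splines with 5 degrees of freedom each. Pairs of probes at least 300 bases apart on a transcript gave the 5′ minus 3′ difference, with an interval from 2000 bootstrap draws of transcripts. The alternatives planned were normexp background correction (offset 50), quantile normalization, scaling on the median of probes well above background on all arrays, 3 other filters on dim genes, the mean over probes or each probe by itself, the deposited table as it stands, and thresholds of 3-fold and 1.5-fold. A further 3 were chosen after seeing the data: removal of the spline trend, a floor at the 95th percentile of olfactory receptor levels (-1.17), and scaling on bright spike-in probes. Where a sign is said to depend on the scaling, the deposited table, which is not scaled, is counted among the scalings. The scripts were run on data simulated with noise of SD 0.1 (log2) per gene. Of 100 genes simulated at 3-fold in each comparison, 100 passed 2-fold, and of 100 at 1.5-fold, 0 did, with 0 false calls among the other genes. That noise is far below 2-fold and leaves out culture, RNA and labelling. The result therefore checks the code and gives no error rate for the counts. A list of 16 genes simulated 3-fold lower had medians of -1.56, -1.63 and -1.57. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, patsy 1.0.2 and matplotlib 3.10.9, with random seed 7.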

Results

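The expression of genes was measured in HMEC-1, a line of human dermal microvascular endothelial cells immortalised with a viral large T antigen, after 72 h of culture with 0, 0.1 or 1 µM erlotinib. Erlotinib is an inhibitor of the tyrosine kinase of the epidermal growth factor receptor (EGFR), used against lung cancer, and the series addresses the purpuric skin eruption seen under this drug and the part that IQGAP1 plays in it. IQGAP1 is a scaffold protein that binds actin, calmodulin, CDC42, RAC1, β-catenin and kinases of the ERK pathway. There was 1 array for each dose, so the differences have no replicate check, and values are described without a test. Of 50599 probes, 74.99% were well above background at 0 µM, 83.0% at 0.1 µM and 78.0% at 1 µM. The 75th percentile of signal was 810, 1391 and 1004 in the same order, and values are log2 signals relative to that percentile of their own array. The only error these arrays give is that between the 10 spots of a repeated probe, with a median SD of 0.10, 0.08 and 0.07 (log2), which leaves out culture, RNA extraction and labelling.

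IQGAP1 signal was 2.11-fold higher at 1 µM than at 0 µM (log2 difference 1.07) and 2.67-fold higher at 0.1 µM (1.42). Its level was 3.17 at 0 µM, 4.58 at 0.1 µM and 4.24 at 1 µM, on a single probe for transcript NM_003870 at position 7149 of the transcript (hg19, chromosome 15, 91045415 to 91045474). The related scaffolds IQGAP2 and IQGAP3 lay on the other side, at -0.89 and -0.81 for 1 µM and -0.48 and -0.86 for 0.1 µM. IQGAP2 at 0.1 µM was above 0 with the unscaled table and with spike-in scaling. Of the 18 measured genes of the IQGAP family and IQGAP1's partners, 2 were at least 2-fold higher and 2 at least 2-fold lower at 1 µM. The higher genes were IQGAP1 and CLIP1, a microtubule plus-end protein (1.72), and the lower ones were EZR, which links actin to the membrane (-1.17), and CALM3, a calmodulin gene (-1.08). The median of this list was -0.66, at percentile 5.40 of 10000 random lists of the same size matched on signal. The position of a probe along its transcript, its GC content and its signal were related to the differences, as given below. The joint trend on all of these is called the position trend from here on, though GC content and signal were more strongly correlated with the differences at 1 µM. With this trend removed IQGAP1 was 0.96 higher at both doses, just under 2-fold.

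The target of the drug, EGFR, was level between 1 and 0 µM (0.00) and 0.38 higher at 0.1 µM on its brightest probe. A probe of a shorter EGFR transcript read -0.37 and -0.39, and another, dim probe 0.01 and -0.13. Over the processing settings EGFR ranged from -0.32 to 0.31 at 1 µM and from -0.28 to 1.16 at 0.1 µM, so its direction is not settled. ERBB2 was at -0.37 for 1 µM and -0.48 for 0.1 µM on a probe with 10 spots and at 0.10 and -0.21 on another, and ERBB3, with a low signal, was at 0.48 and 0.71 on one probe and -0.17 and -0.54 on another. Among the 12 measured ERBB receptors and ligands, the ligand amphiregulin (AREG) was 3.73-fold lower at 1 µM and ERRFI1, a feedback inhibitor of EGFR, was 2.12-fold higher. The level of AREG at 1 µM (-1.52) was within the range of olfactory receptor genes. The median of this list was -0.08 at 1 µM (percentile 50.4) and -0.06 at 0.1 µM (percentile 78.1), and its sign depended on the scaling.

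Between 1 and 0 µM, the genes that report ERK pathway output were lower as a group. All 16 measured members lay below 0 and 10 were at least 2-fold lower, with a median of -1.36, below every one of the 10000 random lists. The transcription factor EGR1 was 91.9-fold lower (-6.52), to a level of -2.41 within the range of olfactory receptor genes, so the fold is not exact. FOSL1 was at -2.66, the ERK phosphatases DUSP5 -2.33 and DUSP6 -1.56, PHLDA1 -2.32, and the ETS factors ETV4 -1.42 and ETV5 -1.35. MYC was at -0.30 and CCND1, the cyclin D1 gene, at -1.02. In the other direction, genes of the integrated stress and unfolded protein response had a median of 0.92, above all random lists (0.53 with each probe by itself), with 9 of 23 at least 2-fold higher and none at least 2-fold lower.

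Within the stress response list, DDIT3, which encodes the transcription factor CHOP, was 11.2-fold higher at 1 µM (3.49), the cystine transporter SLC7A11 6.88-fold (2.78), asparagine synthetase (ASNS) 3.91-fold (1.97) and the endoplasmic reticulum chaperone HSPA5 2.89-fold (1.53). HERPUD1 (1.31) and TRIB3 (1.26) were also higher, and CRELD2 was at -0.64. Targets of the aryl hydrocarbon receptor and NRF2 had a median of 0.55, above all random lists, with 6 of 18 at least 2-fold higher, and of 0.935 with the position trend removed. They included AKR1C1 (2.98), the receptor's repressor AHRR (2.19), CYP1B1 (1.82) and GCLC, the catalytic subunit of the first enzyme of glutathione synthesis (1.78). AHRR was within the olfactory receptor range on both arrays (-4.44 at 0 µM and -2.25 at 1 µM), and CYP1B1 at 0 µM (-2.38). SLC7A11 belongs to both lists.

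**Figure D1:**
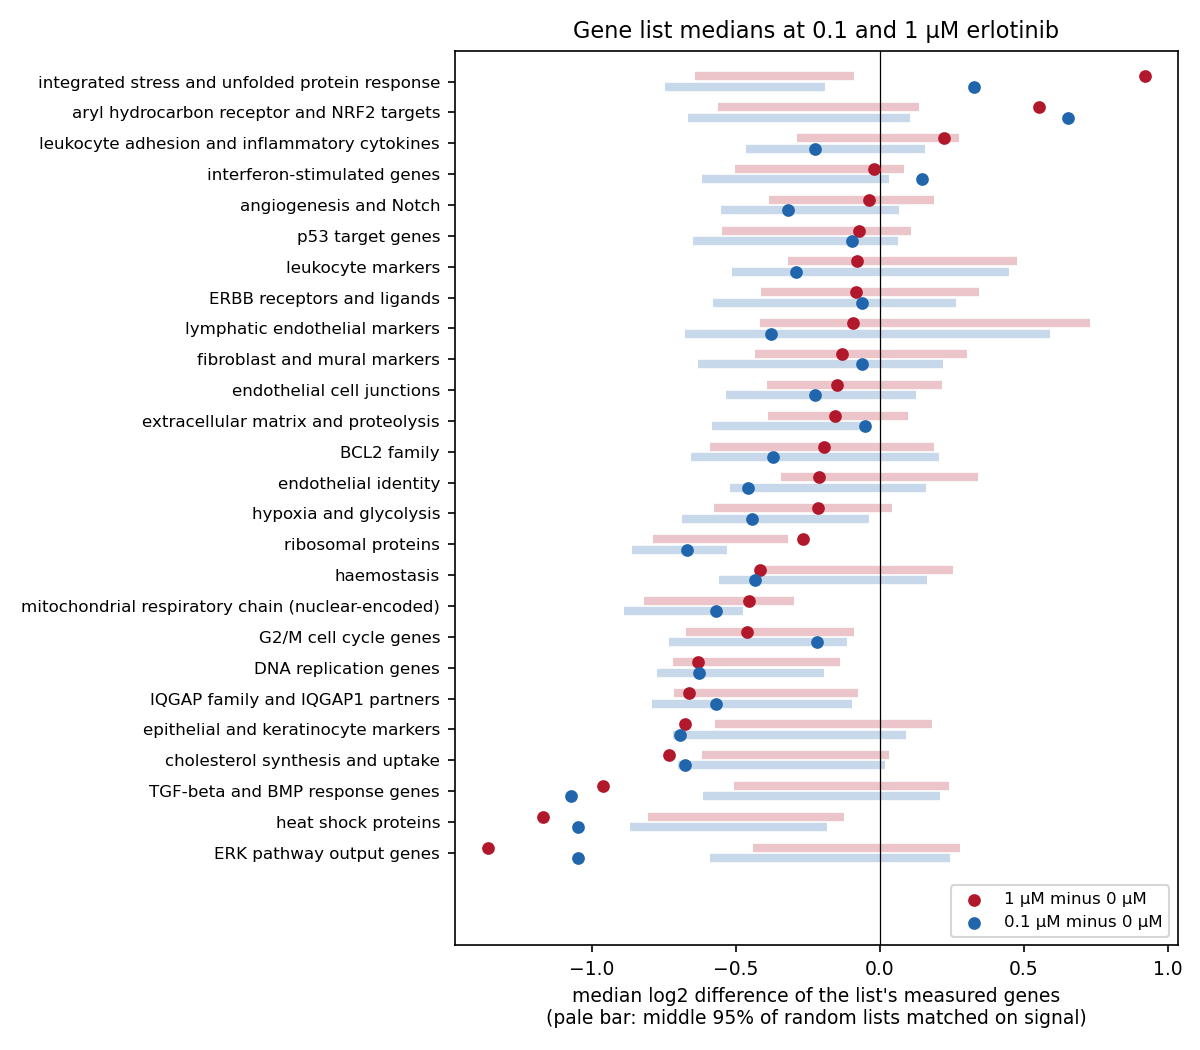
Median log2 difference from the 0 µM array (x axis) of the measured genes of each of 26 gene lists (y axis), at 1 µM (red) and 0.1 µM (blue) erlotinib, 1 array per dose; pale bars span the middle 95% of random lists matched on signal. ERK pathway output genes lie at -1.36 and -1.05 and stress response genes at 0.92 and 0.33, outside the bars at both doses, and the sign of most lists near 0 depends on the scaling.

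Heat shock proteins and genes responding to TGF-β and BMP were lower at 1 µM. The heat shock list had a median of -1.17, below all random lists (-0.78 with the position trend removed), with 8 of 14 at least 2-fold lower, among them the chaperones HSPA8 (-2.25) and HSPA1A (-1.44) and the co-chaperones BAG3 (-1.59) and DNAJB1 (-1.36). Of the 16 measured TGF-β and BMP response genes 8 were at least 2-fold lower, with a median of -0.96, below all random lists. The matrix protein gene TGFBI was 12.5-fold lower (-3.64), to a level of -2.35 that is also within that range, CCN1 was at -2.31, CCN2 at -2.09 and the BMP-induced repressors ID3 and ID1 at -1.77 and -1.37. The median of cholesterol synthesis and uptake genes was -0.73 (percentile 0.45), with 7 of 20 at least 2-fold lower, including the sterol synthesis genes LSS (-1.40) and FDPS (-1.09).

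Genes of blood vessel function were less uniform at 1 µM. Of 18 measured genes of endothelial junctions none was 2-fold apart, and the median was -0.15 (percentile 39.0) with a sign that depended on the scaling. VE-cadherin (CDH5) was at -0.41, PECAM1 at -0.86 and the tight junction scaffold TJP1 at 0.66. Over the processing settings TJP1 ranged from 0.04 to 0.97. The level of PECAM1 was -2.36 at 0 µM and -3.22 at 1 µM and that of CDH5 -1.05 and -1.45, in the range of olfactory receptor genes, whose 95th percentile was -0.85 and -1.15 on these arrays. The haemostasis list had a median of -0.42 (percentile 2.34), and its members past 2-fold were TFPI2, an inhibitor of coagulation proteases (-1.94), and SERPINE2, an inhibitor of thrombin (-1.51). The matrix and proteolysis list held the urokinase receptor PLAUR (-1.90), the basement membrane collagen COL4A1 (-1.14) and the stromelysin MMP10 (1.27), with a median of -0.15 (percentile 52.8). MMP10 was within the olfactory receptor range on both arrays (-4.53 at 0 µM and -3.26 at 1 µM). The angiogenesis and Notch list had a median of -0.04 (percentile 72.2), with NRP1 at -1.08 and EFNB2 at -1.03. Both medians changed sign with the scaling.

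Leukocyte adhesion and cytokine genes went both ways, with 4 of 21 at least 2-fold higher and 2 at least 2-fold lower. BIRC3, an NF-κB target that inhibits cell death, was at 2.30, IL1B at 1.74, CXCL2 at 1.29, IL11 at -2.72 and CXCL8 at -1.62. IL1B (-3.21 at 0 µM and -1.48 at 1 µM) and CXCL8 (-2.84 and -4.46) were within the olfactory receptor range on both arrays. BIRC3 was within it at 0 µM (-2.44) and IL11 at 1 µM (-3.24). The median of the list was 0.22 (percentile 95.1), with a sign that depended on the scaling. SELE, VCAM1 and PTGS2 were not well above background on both arrays. Interferon-stimulated genes had a median of -0.02 (percentile 91.4), with a sign that depended on the scaling, and split between IFI44L (1.53), IFIH1 (1.44) and IFI27 (1.29) on one side and ISG15 (-1.37) and OASL (-1.08) on the other. IFIH1 was within the olfactory receptor range at 0 µM (-1.76).

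Cell cycle genes were split as well. In the G2/M list 8 of 24 genes were at least 2-fold lower, such as PLK1 (-1.60), CCNB1 (-1.49) and AURKB (-1.33), and 3 were at least 2-fold higher, TOP2A (1.25), CENPF (1.22) and ASPM (1.15). The median was -0.46 (percentile 33.4). With the position trend removed TOP2A, CENPF, ASPM, PLK1 and CCNB1 were at 1.07, 1.02, 0.81, -1.19 and -1.09. DNA replication genes had a median of -0.63 (percentile 7.47), with 4 of 22 at least 2-fold lower, among them GINS2 (-1.19) and FEN1 (-1.12). The p53 target list had a median of -0.07 (percentile 85.4), with RRM2B at 1.71, GDF15 at 1.57 and TP53I3 at -1.63, and the BCL2 family -0.20 (percentile 58.8), with MCL1 at -1.32. The hypoxia and glycolysis list was at -0.21 (percentile 66.9), with CA9 at -1.65 and PDK1 at 1.29. The sign of these last 3 medians depended on the scaling. RRM2B (-2.96 at 0 µM and -1.26 at 1 µM) and CA9 (-1.79 and -3.44) were within the olfactory receptor range on both arrays.

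Among markers of cell types, the epithelial and keratinocyte list had a median of -0.68 (percentile 0.58; -0.355 with the position trend removed, percentile 6.05), with KRT8 (-1.59), KRT17 (-1.40), KRT18 (-1.29) and KRT14 (-1.16) at least 2-fold lower. For KRT14 the mean over its probes was 0.14. Both KRT14 and KRT17 had a level of -1.73 at 1 µM, within the olfactory receptor range. The levels of KRT7, KRT18, SFN and KRT8 at 0 µM were 8.23, 7.43, 6.31 and 4.65. On the same array EPCAM, CDH1 and TP63 were not well above background. Endothelial identity genes were at -0.21 (percentile 14.9), with endoglin (ENG) at -0.97 and none of the 13 measured of 22 at least 2-fold apart. Lymphatic endothelial markers were at -0.09 (percentile 29.1). Fibroblast and mural markers were at -0.13 (percentile 42.6), or -0.48 with the position trend removed (percentile 1.74), with CNN1 at 1.89 and MYL9 at -1.08. Leukocyte markers were at -0.08 (percentile 36.8). These 4 medians changed sign with the scaling. So did the ribosomal proteins (-0.27, percentile 99.2, and -0.05 with the position trend removed, percentile 67.8) and the nuclear-encoded genes of the mitochondrial respiratory chain (-0.45, percentile 75.6). CNN1 (-4.80 at 0 µM and -2.91 at 1 µM) was within the olfactory receptor range on both arrays. Of the endothelial identity genes, so were PECAM1, CDH5, VWF, KDR, EMCN, ROBO4, CLEC14A and ESAM, while ENG, NOS3, EGFL7, MMRN2 and MCAM were above it. TIE1, FLI1, ECSCR, TAL1 and SOX18 were not well above background on any array. With most endothelial markers this dim beside the keratins, these arrays alone do not establish the endothelial identity of the cells.

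Genes that this cell type should lack gave a measure of the detection flag. Of 363 olfactory receptor genes, 60.9% were well above background at 0 µM, 66.7% at 0.1 µM and 61.2% at 1 µM, at median levels of -4.31, -4.47 and -4.18, so that a dim gene passing the flag need not be expressed. Their median difference was -0.04 at 1 µM and -0.19 at 0.1 µM. Median differences of markers of other cell types at 1 and 0.1 µM were -0.18 and -0.34 for red cells, -0.08 and -0.24 for myeloid cells, -0.06 and -0.43 for T and NK cells, -0.17 and -0.16 for B cells, -0.07 and -0.30 for hepatocytes, -0.09 and -0.32 for neurons and glia, 0.05 and -0.44 for testis germ cells, and -0.16 and -0.62 for striated muscle. The levels of the brightest members, among them CD4 in the T and NK set and DCN among fibroblast markers, were 4.10 and 2.59 as means over the arrays.

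Among genes of at least median signal, those farthest apart between 1 and 0 µM, beyond the ones already named, were ULBP1, a ligand of the NKG2D receptor of natural killer cells (10.7-fold higher), NIBAN1 (8.10-fold), AKR1C8 (6.83-fold), ATP6AP1L (5.42-fold), ANKRD36B (5.20-fold), PDE4D (4.97-fold), SELENOP (4.84-fold), GABPB1-AS1 (4.80-fold) and the nuclear RNA MALAT1 (4.76-fold). The levels of ULBP1 (-2.67), NIBAN1 (-2.57), ATP6AP1L (-2.25), ANKRD36B (-2.23), GABPB1-AS1 (-2.06), SELENOP (-1.96), SLC7A11 (-1.16) and PDE4D (-0.90) at 0 µM were within the olfactory receptor range. On the lower side stood DKK1, an inhibitor of WNT signalling (8.53-fold), DMBT1 (7.56-fold), the transglutaminase TGM2 (7.27-fold), MALL (6.45-fold) and the TWEAK receptor TNFRSF12A (6.35-fold). DMBT1 (-1.26) and TGM2 (-1.18) were within that range at 1 µM. On hg19 the DDIT3 probe spans chromosome 12, 57911200 to 57911526, the EGR1 probe chromosome 5, 137804891 to 137804950, and the TGFBI probe chromosome 5, 135399343 to 135399402. Genes well above background at 1 µM but not at 0 µM included MMAA (at least 16.4-fold higher), ALPK2 (at least 10.9-fold) and ITIH2 (at least 10.4-fold), and those at 0 µM but not at 1 µM included FAM99B (at least 18.3-fold lower), HRH4 (at least 11.9-fold) and PWAR1 (at least 8.99-fold). For these bounds the dim probe was set to the higher of its own signal and the lowest signal well above background on its array.

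In all, 22660 genes were measured at both 1 and 0 µM. Of these 1583 were at least 2-fold higher and 1476 at least 2-fold lower, and 65.9% lay within 1.5-fold. The median of all genes was -0.10, and it was -0.48 in the brightest 20% of genes. Across genes the differences fell with the signal (Spearman's rho -0.27) and with the GC content of the probe (-0.24). Differences were higher for probes far along their transcripts (Spearman's rho 0.14 across genes), with a median of 0.24 in the 10% of genes whose probes lay farthest along. The rise was not steady, as the median fell from -0.10 in the nearest 10% to -0.20 in the 4th 10%. Within 3283 transcripts with a pair of probes at least 300 bases apart, the probe nearer the 5′ end read lower relative to the one nearer the 3′ end at 1 µM than at 0 µM, by a median of -0.11 (95% bootstrap interval -0.13 to -0.09). The counts depend on scaling, and the unscaled signals of the deposited table gave 2875 higher and 504 lower genes. Scaling on bright spike-in probes, which differed by 0.02 between these arrays after the main scaling, gave 1567 and 1489.

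**Figure D2:**
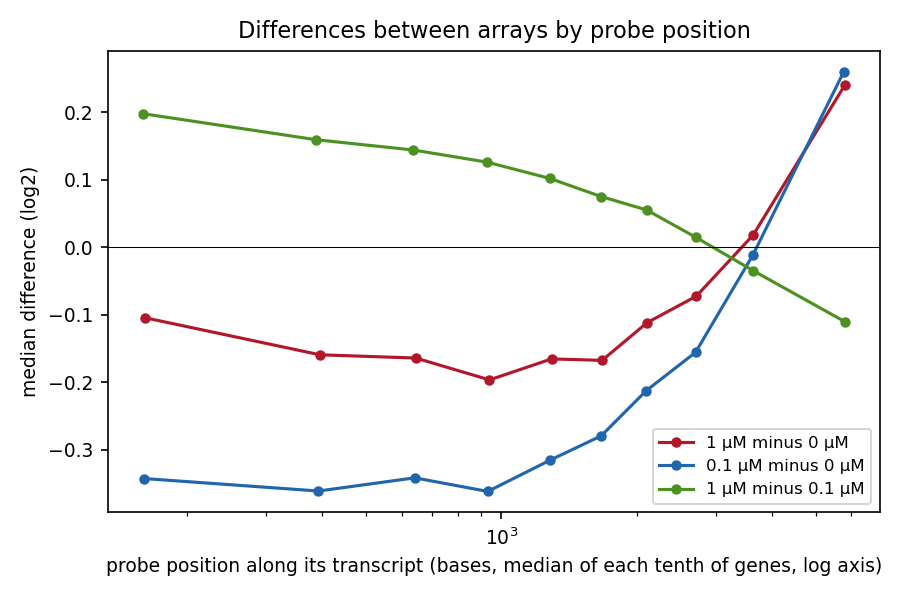
Median log2 difference (y axis) of the genes in each 10% of probe position along the transcript (x axis, bases, log axis), for 1 minus 0 µM (red), 0.1 minus 0 µM (blue) and 1 minus 0.1 µM (green), 1 array per dose. In the farthest 10% the medians are 0.24, 0.26 and -0.11; all points of a line move up or down together when the scaling differs.

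At 0.1 µM the lists of ERK output, stress response, aryl hydrocarbon receptor and NRF2, heat shock, and TGF-β and BMP response genes lay outside the middle 95% of random lists, as they did at 1 µM. ERK pathway output genes had a median of -1.05, below all random lists, with 8 of 16 at least 2-fold lower, and EGR1 was at -2.76, FOSL1 at -2.23, DUSP5 at -1.68 and IER3 at -1.41. The stress response list had a median of 0.33, above 99.99% of random lists (0.035 with each probe by itself), with 5 of 23 at least 2-fold higher, led by SLC7A11 (2.77) and DDIT3 (2.73). Targets of the aryl hydrocarbon receptor and NRF2 were at 0.65, above all random lists, with AKR1C1 at 2.61, AHRR at 1.97 and GCLC at 1.90. Heat shock proteins (-1.05, percentile 0.10), with HSPA8 at -2.29 and HSPA1A at -1.95, and TGF-β and BMP response genes (-1.07, below all random lists), with TGFBI at -3.52, ID3 at -1.76 and CCN1 at -1.64, were lower. The levels of DUSP5 (-1.36), AHRR (-2.47) and TGFBI (-2.23) at 0.1 µM were within the olfactory receptor range.

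Interferon-stimulated genes at 0.1 µM had a median of 0.15 (percentile 99.2), with IFI44L at 1.73 and IFIH1 at 1.72 and ISG15 at -1.11. In the G2/M list 7 of 24 genes were at least 2-fold higher, led by TOP2A (1.76), ASPM (1.69) and CENPF (1.67), and 5 at least 2-fold lower, including PLK1 (-1.52), with a median of -0.22 (percentile 92.1). Cholesterol genes were at -0.68 (percentile 3.63), with FDPS at -1.37 and LSS at -1.13, epithelial and keratinocyte markers at -0.69 (percentile 3.21), with KRT14 at -1.53 and KRT8 at -1.52, haemostasis genes at -0.43 (percentile 11.96), with TFPI2 at -1.63, DNA replication genes at -0.63 (percentile 23.2) and the IQGAP family and partners at -0.57 (percentile 33.5). Endothelial identity genes were at -0.46 (percentile 6.13), with 3 of 15 at least 2-fold lower: KDR, the main VEGF receptor (-1.11), ENG (-1.12) and FLT1 transcript NM_001160031 (-3.06). KDR (-2.89 at 0 µM and -4.01 at 0.1 µM), FLT1 (-2.90 and -5.96), PECAM1, VWF and ESAM also had levels within the olfactory receptor range, while MCAM (3.65 and 2.79) and EGFL7 (2.13 and 2.02) were above it. The FLT1 transcript was not well above background at 1 µM, where it was at least 5.86-fold lower than at 0 µM.

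Endothelial junctions at 0.1 µM were at -0.22 (percentile 54.4), lymphatic markers at -0.38 (percentile 20.01), fibroblast and mural markers at -0.06 (percentile 81.8), leukocyte markers at -0.29 (percentile 27.0), adhesion and cytokine genes at -0.23 (percentile 43.2), p53 targets at -0.10 (percentile 90.6), the BCL2 family at -0.37 (percentile 34.1), hypoxia and glycolysis at -0.44 (percentile 38.1), matrix and proteolysis at -0.05 (percentile 96.9), angiogenesis and Notch at -0.32 (percentile 35.9), ribosomal proteins at -0.67 (percentile 68.8) and the respiratory chain at -0.57 (percentile 89.6). The sign at 0.1 µM held in every scaling for the ERK output, stress response, aryl hydrocarbon receptor and NRF2, heat shock, TGF-β and BMP and interferon lists, and flipped in at least 1 scaling for the other 20. The size did not hold: with the unscaled table the ERK output, heat shock and TGF-β and BMP medians were -0.27, -0.27 and -0.29, beside a median of all genes of 0.53. Single genes of at least median signal far apart at 0.1 µM, beyond those named, included HINT3 (2.88), ZNF652 (2.55), ZNF33B (2.53), KNTC1 (2.48) and VPS13C (2.48) on the higher side, and the prostaglandin E synthase PTGES (-2.43), ACTL8 (-2.41), MRPL12 (-2.37), SERTAD1 (-2.28) and the ERK phosphatase DUSP2 (-2.24) on the lower side. Over the processing settings VPS13C ranged from 1.31 to 3.26.

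Of 22916 genes measured at both 0.1 and 0 µM, 1750 were at least 2-fold higher and 2137 at least 2-fold lower, and the median of all genes was -0.25. The relation with position alone was steeper than at 1 µM (Spearman's rho 0.24), as was that with GC content (-0.33), while that with signal was weaker (-0.16). The 5′ probe of a transcript read lower relative to the 3′ probe by a median of -0.19 (95% bootstrap interval -0.21 to -0.18). Bright spike-in probes, whose input amounts are not given in the sources used here, differed by -0.75 between these arrays after scaling, and scaling on them gave 5336 higher and 172 lower genes with a median of all genes of 0.49.

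**Figure D3:**
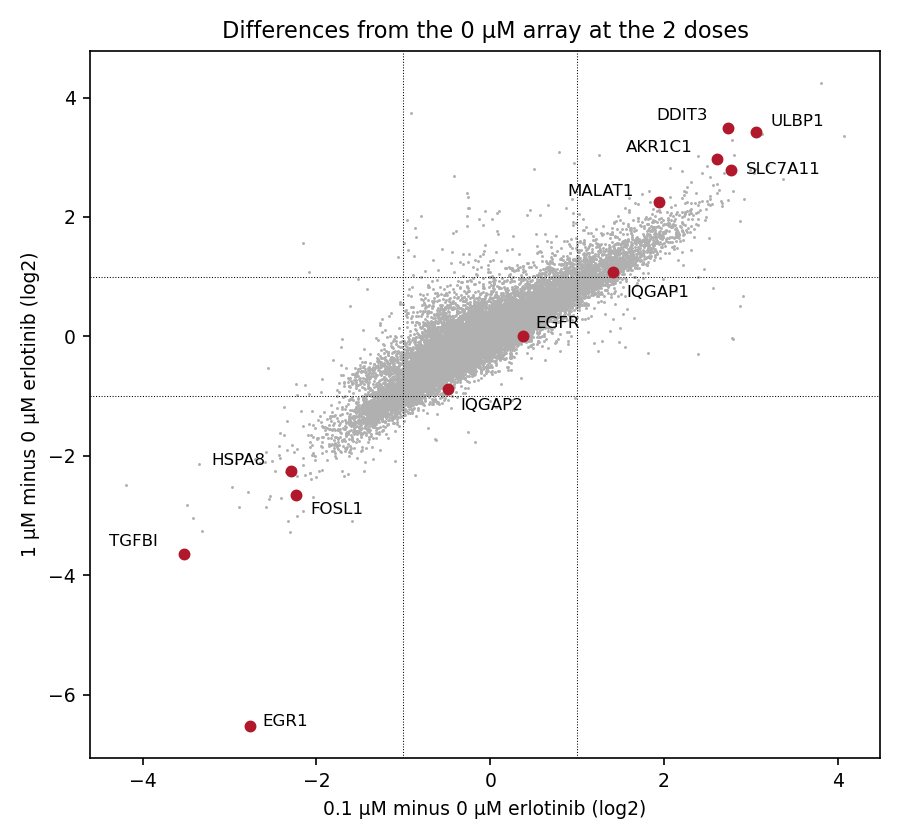
Log2 difference of each gene from the 0 µM array at 0.1 µM erlotinib (x axis) and at 1 µM (y axis), 1 array per dose, with 12 genes marked in red and dotted lines at 2-fold. IQGAP1 lies at 1.42 and 1.07, DDIT3 at 2.73 and 3.49, TGFBI at -3.52 and -3.64, and EGR1 at -2.76 and -6.52.

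The 1 and 0.1 µM arrays were closer to each other than either was to the 0 µM array. Among 23573 genes, 351 were at least 2-fold higher and 61 at least 2-fold lower at 1 µM than at 0.1 µM, and 92.6% lay within 1.5-fold. The split turned with the unscaled table (116 higher, 318 lower) and with spike-in scaling (70 and 2276), which shift all genes together, to medians of -0.39 and -0.67 from 0.08. Among genes of at least median signal, EGR1 was the farthest apart (-3.76), followed on the lower side by TXNIP (-1.10), GNAL (-1.03), the TGF-β and YAP target CCN2 (-0.996) and HINT3 (-0.94). On the higher side stood the small nuclear RNAs RNVU1-18 (2.52) and RN7SK (1.85), the vasoconstrictor peptide gene EDN2 (1.53), PYY2 (1.46) and CCKBR (1.44). Whether the labelling reads small nuclear RNAs fully was not tested. IQGAP1 was at -0.34, about the SD of 0.34 over all genes in this comparison.

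Stress response genes were higher at 1 than at 0.1 µM in 22 of 23 cases, with a median of 0.43, above all random lists, a sign that flipped with the common shift of the unscaled table and spike-in scaling. ERK output genes were lower still at 1 µM (median -0.28, below all random lists), with PHLDA1 at -1.45. The level of PHLDA1 was within the olfactory receptor range on both of these arrays (-1.98 at 0.1 µM and -3.43 at 1 µM). G2/M genes (-0.32, below all random lists) and interferon-stimulated genes (-0.15, percentile 0.05) were lower. With the position trend removed these medians were -0.16 and -0.04, smaller but still below the middle 95% of random lists. All 25 ribosomal protein genes were higher (0.36, above all random lists), with a sign that flipped with the same shift, which leaves places among random lists as they are. The sign flipped likewise for adhesion and cytokine genes (0.29, percentile 99.8), the BCL2 family (0.14, percentile 98.7) and the hypoxia and glycolysis list (0.17, percentile 98.5). With the position trend removed the BCL2 family was at percentile 91.0, inside the middle 95% of random lists. In the hypoxia list adrenomedullin (ADM) was 1.29 higher. In the matrix list MMP10, within the olfactory receptor range on both arrays, was 1.27 higher. The matrix (-0.05, percentile 0.94), cholesterol (-0.10, percentile 1.27), haemostasis (-0.08, percentile 2.01) and DNA replication (-0.05, percentile 2.52) medians were below 0, and with the position trend removed all 4 were above 0 and inside the middle 95% of random lists.

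**Figure D4:**
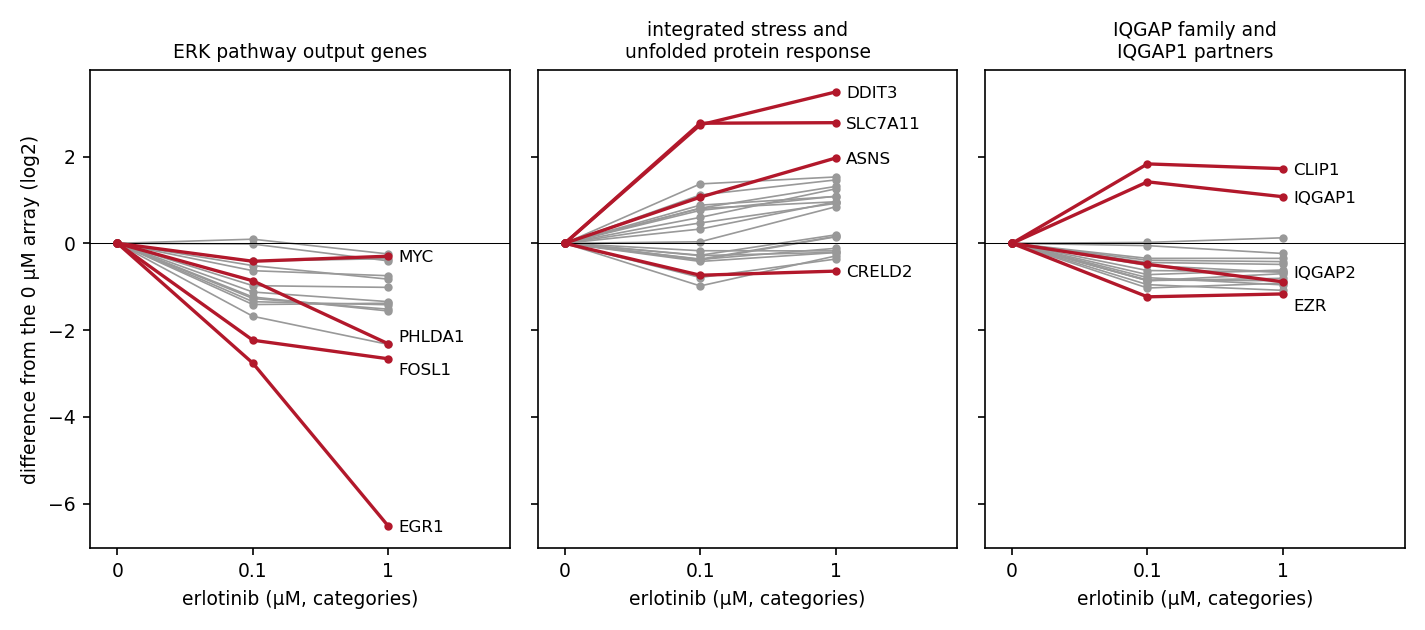
Log2 difference from the 0 µM array (y axis) at each erlotinib dose (x axis, drawn as categories) for the measured genes of 3 lists, 1 line per gene and 1 array per dose, with named genes in red. EGR1 lies at -2.76 at 0.1 µM and -6.52 at 1 µM, DDIT3 at 2.73 and 3.49, and IQGAP1 at 1.42 and 1.07.

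The differences of the 2 doses from the 0 µM array were correlated across 22638 genes (Pearson's r 0.90, Spearman's rho 0.88), where genes are not independent replicates. Both share the single 0 µM array, and arrays simulated with spot noise alone and no effect gave r 0.62, with a covariance of 0.0098 beside the observed 0.44. With the 0.1 µM array as the common reference the observed r was 0.39 (0.47 simulated) and the covariance 0.092 (0.0067), and with the 1 µM array 0.05 (0.40) and 0.010 (0.0054), so that r lay above its simulated value with the 0 µM array alone. At both doses 1257 genes were at least 2-fold higher and 1245 at least 2-fold lower, where independent lists would share 122 and 135. These counts were 2675 and 123 with the unscaled table, and 1487 and 146 with spike-in scaling. Only 3 genes were past 2-fold in opposite directions. The control array cannot be split, so part of this excess may come from it. Of the 3050 genes at least 2-fold apart between 1 and 0 µM, the 0.1 µM value lay between the other doses for 1294 (42.4%), beyond the 1 µM value for 1700 and on the opposite side of 0 µM for 56.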

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

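Of the named genes past 2-fold, 109 of 110 at 1 µM, 114 of 114 at 0.1 µM and 13 of 13 between the doses kept their sign in every setting, and 68, 53 and 4 stayed past 2-fold in all of them. These genes were chosen for large differences on these arrays, some also for agreeing probes, so a kept sign was likely. The filters on dim genes only keep or drop a gene, so these settings could not change a sign. Of the other probes of measured genes, 66.8%, 71.1% and 65.7% differed in the same direction as the brightest. For genes past 2-fold these shares were 83.6%, 82.9% and 71.4%. IQGAP1 ranged from 0.96 to 1.52 at 1 µM and from 0.96 to 2.20 at 0.1 µM. Of the 26 list medians, 11, 6 and 4 kept their sign in every setting for 1 minus 0, 0.1 minus 0 and 1 minus 0.1 µM. The removal of the trend with position, GC and signal, the floor at olfactory receptor levels and the spike-in scaling were chosen after seeing the data. Signal over background limits the dim genes most, since the scanner's flag passes most olfactory receptor genes. No paired analysis was possible because each dose has a single array and no test was made, and for the same reason no array could be left out in turn. The slide and scan were shared, so no batch could be compared. In the values below, counts are genes at least 2-fold apart unless another threshold is named, and the cause was not tested except where a setting's filter or threshold itself sets the count.

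Filters and thresholds act by construction. With no detection filter, 2512 genes were higher at 1 µM, 2703 higher at 0.1 µM, and 765 higher and 419 lower between the doses; 0.1 µM lay between the others for 2026 genes and the correlation of the doses was 0.80. With genes in the upper part of the signal range these were 700, 965, 34 and 7, then 760 genes and 0.95, with 634 higher at both doses. Above the olfactory receptor range they were 779, 1007, 33 and 6, then 773 genes and 0.95, with 717 higher at both doses. With genes well above background on all 3 arrays, 39 were lower between the doses. At 3-fold, 394 were higher and 199 lower at 1 µM, 543 and 285 at 0.1 µM, and 96 and 22 between the doses, with 286 in dose order, 297 higher and 142 lower at both doses. At 1.5-fold these were 3458 and 4278, 3356 and 6183, 1518 and 235, then 3116, 2747 and 3905. Each probe counted by itself gave 2584 higher at 1 µM, 2760 higher and 3313 lower at 0.1 µM, 666 and 125 between the doses, 2064 in dose order and 2023 higher at both doses.

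The scaling and background settings moved these values, and the cause was not tested. With normexp, 882 genes were higher at 1 µM, 1117 higher at 0.1 µM, and 164 higher and 13 lower between the doses, with 814 in dose order and 733 higher at both doses. With quantile normalization, 806 were lower at 1 µM, 1239 lower at 0.1 µM and 594 lower at both doses. The deposited table as it stands gave 2875 higher and 504 lower at 1 µM, 5648 and 153 at 0.1 µM, and 116 and 318 between the doses, with 817 in dose order, 2675 higher and 123 lower at both doses. Spike-in scaling gave 5336 higher and 172 lower at 0.1 µM, 70 and 2276 between the doses, and 146 lower at both doses. With the trend removed, 913 were higher at 0.1 µM and 702 higher at both doses.

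The share of higher genes among those past 2-fold was 51.7% at 1 µM, 45.0% at 0.1 µM and 85.2% between the doses. It was 66.3% and 61.6% at the 2 doses with quantile normalization, 39.6% at 1 µM with the median of detected probes, 85.1%, 97.4% and 26.7% with the deposited table, and 96.9% at 0.1 µM and 2.98% between the doses with spike-in scaling. With the trend removed it was 30.3% at 0.1 µM. The median of all genes at 1 µM, at 0.1 µM and between the doses was -0.10, -0.25 and 0.08, and it was 0.20, 0.53 and -0.39 with the deposited table, -0.11, 0.49 and -0.67 with spike-in scaling, and -0.10, -0.14 and 0.00 with quantile normalization.

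Some signs reversed, and the cause was not tested. The mean over probes gave 0.14 for KRT14 at 1 µM. Between the doses, the deposited table gave medians of -0.33 for the BCL2 family, -0.30 for hypoxia and glycolysis, -0.0452 for the stress response, -0.18 for adhesion and cytokine genes and -0.11 for ribosomal proteins, and spike-in scaling gave -0.61, -0.58, -0.32, -0.46 and -0.38 for the same lists. Ribosomal proteins at 1 µM were at 0.0271 with quantile normalization and 0.0429 with the deposited table, and between the doses at 0.00 with quantile normalization. The list of extracellular matrix and proteolysis between the doses was at 0.0322 with the mean over probes, 0.0186 with each probe by itself and 0.0005 with the trend removed. In that comparison haemostasis was at 0.0383 with each probe by itself and 0.0344 with the trend removed, and cholesterol genes at 0.0025 with the trend removed.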

Other observations

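The gene groups in the next 2 paragraphs, the tests of the 0 µM array and the test of probes far apart were chosen after their values were seen, while the other tests were written before. The signal of replication-dependent histone genes was lower at both doses, and whether the labelling reads their RNA fully was not tested. Of 64 measured, 39 were at least 2-fold lower at 1 µM and 47 at 0.1 µM, with medians of -1.04 and -1.29, below all random lists and below 0 in every scaling (-0.51 at 0.1 µM unscaled). Members such as H2AC13 (-2.04 and -2.15) and H1-5 (-1.82 and -2.05) have similar sequences, so their probes can share signal, and with the position trend removed the medians were -0.48 and -0.69. Of 16 tubulin genes, 12 and 13 were at least 2-fold lower, with medians of -1.48 and -1.51 (-1.26 and -1.19 with the trend removed, -0.73 at 0.1 µM unscaled), among them TUBB3 (-2.16 and -2.15) and TUBB4B (-1.998 and -2.02). Metallothioneins, which bind zinc and copper, had medians of -1.31 at both doses (-0.77 and -0.69 with the trend removed, -0.53 at 0.1 µM unscaled), with 6 of 9 at least 2-fold lower, MT1X at -1.62 and -1.31 and MT1F at 0.46 and 0.27.

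The aldo-keto reductase genes of family 1C were all higher, with medians of 2.30 at 1 µM and 1.92 at 0.1 µM for 4 of 4 genes, but AKR1C1 to AKR1C4 are alike enough to share signal. Transporters of amino acids had medians of 0.37 and 0.02, with SLC1A4 at 1.15 and 0.87. Cytosolic tRNA synthetases split between EPRS1 (1.66 and 1.63) and LARS1 (1.47 and 1.13) on the higher side and MARS1 (-1.21 and -1.21) and HARS1 (-1.18 and -1.17) on the lower, with medians of 0.19 and -0.22. With the trend removed the medians were 0.61 and 0.18. The 0.1 µM median was also above 0 with quantile normalization (0.22), unscaled (0.56) and with spike-in scaling (0.53). It stayed below 0 with normexp (-0.14) and with the median of detected probes (-0.20). Among zinc finger (ZNF) genes, 59 of 406 were at least 2-fold higher and 9 lower at 1 µM, and 78 of 407 higher and 21 lower at 0.1 µM. Their medians of 0.15 and 0.17 were 0.03 and -0.04 with the trend removed, above all random lists both before and after. Small nucleolar RNAs lay higher at 1 than at 0.1 µM in 226 of 245 cases (median 0.37), but their median was -0.10 unscaled and -0.38 with spike-in scaling. Whether the labelling reads these RNAs fully was not tested.

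IQGAP1 was higher at both doses, and its probe lies far along its transcript and has a GC content of 35%. Differences tend to be higher far along transcripts and at low GC content. If the trend with probe position, GC and signal were the whole cause, removing it was predicted to leave less than 0.5 at the smaller difference, and if it had no part, at least 1. The value was 0.96, between these bounds, so the trend may account for a part. The fit adds the parts of position, GC and signal, so a joint effect of position and GC may remain in this value. A deviation of the 0 µM array alone and an effect complete at 0.1 µM both predict a small difference between the doses, and the value of -0.34, beside an SD of 0.34 over genes, cannot tell these apart. Differences between the single cultures were not tested.

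Probes far along their transcripts were higher in both treated arrays, relative to other probes. Position was counted from the 5′ end and transcript lengths were not used. Across genes a far probe therefore cannot be told from a long transcript. If more intact RNA or longer cDNA in these arrays were the cause, the 5′ probe of a transcript should differ upward more than the 3′ probe, and the median of -0.11, of the opposite sign, excludes that direction. Less intact RNA or shorter cDNA in the treated arrays remains open: it predicts a lower 5′ probe, and with probes at least 2000 bases apart the median was -0.20 at 1 µM and -0.37 at 0.1 µM. Any other effect that follows position predicts this too, and with 1 array per dose these cannot be told apart. Within each 20% of probes by GC content the rank correlation with position at 1 µM ran from -0.0806 at the highest GC to 0.293 at the lowest, so GC content may have a part.

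ERK output genes were lower at both doses, as an inhibitor of EGFR could bring about in cells that depend on it. With the trend removed the median at 1 µM was -1.08, below all random lists, so the trend as fitted does not account for the whole difference. The fit adds the parts of position, GC and signal. A part in which position and GC act together could remain, and the random lists were matched on signal alone. A deviation of the 0 µM array alone would leave no difference between the doses. The median there was -0.28, below all random lists, and it does not use the 0 µM array, which by construction cannot account for that part. A deviation of the 0.1 or the 1 µM array alone could give such a difference and was not tested. For the part shared by both doses, the 0.1 µM median of -1.05 (-0.27 unscaled) is predicted both by a deviation of the 0 µM array and by an effect at the low dose, and these cannot be told apart. With 1 culture per dose, a difference in the state of the cultures also remains open.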
